A study of Mus musculus with 4 samples.

How the data were processed

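Neuro-2a cells, a line derived from a mouse neuroblastoma, received deltamethrin at 30 µM or its vehicle (0.1% DMSO) for 24 h, and total RNA was hybridised to Affymetrix Clariom S Mouse arrays, a design that reads each well-annotated gene with 1 probe set made of probes in its constant exons. There were 2 arrays of vehicle-treated cells and 2 arrays of deltamethrin-treated cells. Groups and replicate numbers were taken from the sample titles. RNA integrity numbers above 9 were required and 500 ng of total RNA went into labelling, per the labels' protocols. The deposited values are on a log2 scale, 1 value per probe set and array with 2 decimals. They were made with RMA (robust multi-array average, which corrects background, aligns the arrays' distributions and summarises the probes of a probe set) and Transcriptome Analysis Console, per the submitters' processing notes. The versions and the exact RMA variant are not given in the sources used here. The log2 scale was read from the deposited values, which span 1.92 to 18.75.

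The table held 22206 probe sets. None was marked as a control probe and all were tested. Gene names came from the platform's annotation, with symbols matched by Entrez ID to a RefSeq gene table, and no symbol needed an update. In total 19572 probe sets had 1 symbol, none had several and 2634 were unnamed here. They covered 19505 genes, of which 55 had more than 1 probe set. RMA aligns the arrays' distributions, and the arrays' medians lay between 5.60 and 5.63. The table gave no detection call, so it was not possible to say which dim probe sets were above background. The number of arrays limits the precision: the median standard error (SE) of a log2 fold change was 0.19.

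The comparison was deltamethrin minus vehicle, fitted with limma (version 3.58.1 in R 4.3.3) by lmFit and eBayes at default settings, without a mean-variance trend and without a replicate block. It left 2 residual degrees of freedom per probe set, and moderation added 4.43 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all probe sets, and an adjusted p below 0.05 was called. "Rose", "fell" and "changed" are used for calls. Values are means ± SD or log2 fold changes ± SE with n = 2 arrays per group. Gene lists were tested with camera from limma, which asks whether the members of a list shifted relative to all other genes, with the preset correlation of 0.01. The brightest probe set stood for each gene, and p-values were adjusted over the 36 lists, each with at least 5 measured genes. Members were also counted after adjustment over the list alone. Of the 911 list entries, 99 had no probe set matched here and were not analysed here.

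The test, the 36 lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule took the 12 largest rises and the 12 largest falls among called probe sets. These needed 1 symbol, a mean in the higher group above the median of all probe sets, and both deltamethrin arrays beyond both vehicle arrays. Predicted, clone and large receptor family symbols were left out. It added from each list up to 4 called members of largest change or, where none was called, up to 2 of smallest p, which are described for the called lists. Bdnf, Th, Sqstm1, Map1lc3b, Ddit3, Hmox1, Cyp1a1, Cyp1b1 and the measured Scn genes were always included. Other genes given as examples of a list were chosen after their values were seen.

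The alternatives were the replicate number as a block and a filter that kept probe sets above the 40th percentile of the mean level. Quantile normalization, cyclic loess normalization and median centring were also run, and each array was left out in turn. For the variance there were a mean-variance trend, robust moderation, statistics without moderation and array weights. Other thresholds were a 2-fold minimum, an adjusted p below 0.01 and a test against a 1.2-fold change. A fit with 1 probe set per gene was run as well. For lists, camera was repeated with an estimated correlation, on ranks and on the mean of a gene's probe sets, and fry was run. Leaving out genes held by more than 1 list, a split of calls at a control mean of 10 and 3 further lists were chosen after seeing the data. In the statistics without moderation, 4 probe sets whose arrays did not vary within either group were given no p-value.

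The fit was tested on simulated data with 22206 probe sets and 2 arrays per group. The simulated spreads were drawn from the prior variance of this comparison, without regard to level. The fit recovered 0% of 100 probe sets changed 2-fold and 89% of 100 changed 4-fold, with 2 false calls. In the data a mean-variance trend moved the count of calls from 96 to 806, so these values need not hold for bright or dim probe sets. In a simulation of the list test, 3 of 3 lists shifted by 0.5 on the log2 scale were called and 0 of 33 unshifted lists were. The simulated genes varied independently, so it could not show false calls that correlation between genes would cause. In the data, the estimated correlation was 0.294 for the ATF4 list and 0.304 for the ribosomal protein list. It was 0.144 for mitosis, 0.074 for lysosomes, 0.061 for replication and 0.046 for autophagy. For the NRF2 (-0.019), p53 (-0.026) and immediate early (-0.012) lists it lay below the preset 0.01. These 3 calls were lost with the estimated correlation too, so a correlation above the preset does not account for their loss. In the simulation of the list test, 0 of the 3 shifted lists were called with an estimated correlation, and 2 of 3 with fry.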

Results

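The data were gene expression profiles of Neuro-2a cells, a mouse neuroblastoma line often used as a model of neurons, after exposure to the pyrethroid deltamethrin. Pyrethroids are insecticides that hold voltage-gated sodium channels open. Cells given 30 µM deltamethrin for 24 h were compared with cells given 0.1% DMSO, with 2 arrays in each group. The question was which transcripts differ between exposed and vehicle-treated cells. Nothing in the labels says that the arrays came from separate cultures. The p-values of single genes thus measure only the spread between these samples, which may be technical. Those of camera with the preset correlation compare a list's members with all other genes, so they hardly measure the spread between arrays. No scan date or batch label was used here, so batch and group cannot be told apart. The standard deviation of the difference between arrays was 0.33 for the vehicle pair and 0.37 for the deltamethrin pair on the log2 scale. Between groups it ran from 0.40 to 0.45.

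In deltamethrin-treated cells, gene lists of the ATF4 integrated stress response, NRF2 antioxidant defence, lysosomes, autophagy and ribosomal proteins were higher, and lists of DNA replication and mitosis were lower. These were calls of camera with the preset correlation, and none held with an estimated one (adjusted p = 0.481 to 0.647 with an estimated correlation). For single genes in limma, 79 probe sets rose and 17 fell at an adjusted p below 0.05. The largest rise was that of Lcn2, which encodes the iron-siderophore carrier lipocalin 2, from 3.71 ± 0.60 to 8.66 ± 0.01 (SD, n = 2), a log2 fold change of 4.95 ± 0.29 (SE, adjusted p = 0.00897). Its vehicle level, like that of Ppp1r15a, lay below the array median, so its fold depends on a dim value. Car6, the secreted carbonic anhydrase, rose by 4.32 ± 0.19 (adjusted p = 0.00425). Among the falls, the largest was that of Bnip3, a mitochondrial receptor for mitophagy, which fell by 1.77 ± 0.23 (adjusted p = 0.0464).

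Other large rises were those of Ppp1r15a, which encodes the GADD34 subunit that directs dephosphorylation of eIF2α, at 3.03 ± 0.31, and of Ddit3, the transcription factor CHOP. Ddit3 was read by 2 probe sets, which rose by 2.79 ± 0.26 and 2.57 ± 0.26. Niban1, a stress-induced regulator of translation, rose by 2.81. The TNF-induced gene Tnfaip2 rose by 2.92, and Cox6a2, a cytochrome c oxidase subunit of heart and skeletal muscle, rose by 2.86. Srxn1 (sulfiredoxin, which restores oxidised peroxiredoxins) rose by 2.67 and Cyb5r1, a cytochrome b5 reductase, by 2.73. The set of the 12 largest rises was completed by the corneodesmosin gene Cdsn (2.79), the actin-associated palladin gene Palld (2.75) and the matrix metalloproteinase Mmp19 (2.66).

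The falls were smaller. Rgs4, a brake on G protein signalling in neurons, changed by -1.77 ± 0.20 and E2f7, a repressor of the E2F family, by -1.68 ± 0.16. Transcription regulators among the falls were Lmo3 (-1.55), the histone deacetylase Hdac9 (-1.53) and the ETS factor Etv1 (-1.53). Pdk1, a kinase that inhibits pyruvate dehydrogenase, changed by -1.47 ± 0.17, and the hypoxia-inducible gene Ankrd37 by -1.30 ± 0.17. Rrm2, the small subunit of ribonucleotide reductase, fell by 1.29 ± 0.17. The sulfotransferase gene Chst15 (-1.68), the germ-cell RNA-binding gene Dazl (-1.55) and Siah3 (-1.31) made up the rest. With deltamethrin, the means of Rgs4, Chst15, Lmo3, Pdk1 and Siah3 lay below the array median, so their folds depend on dim values.

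**Figure D1:**
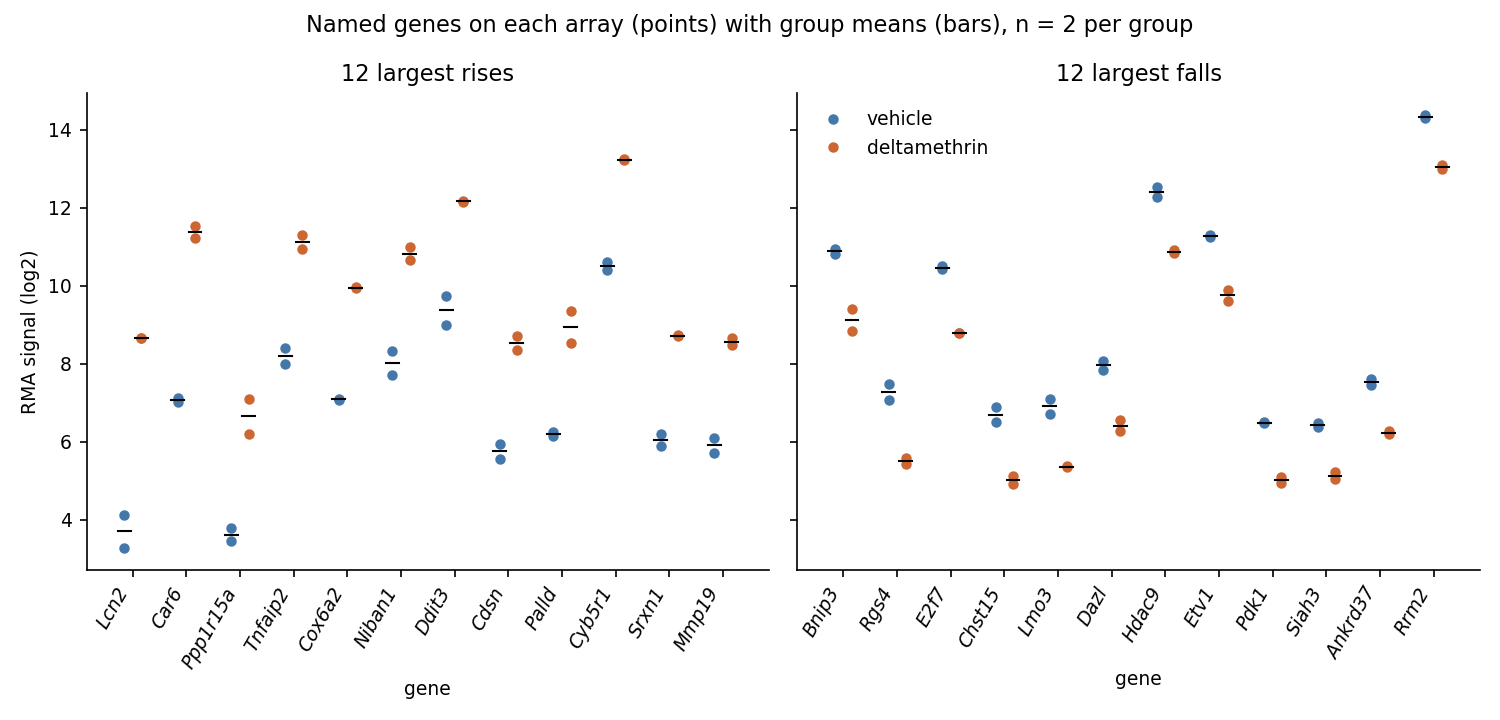
Log2 RMA signal (vertical axis) of the 12 largest rises (left) and 12 largest falls (right) on each array; blue points are the 2 vehicle arrays, orange points the 2 deltamethrin arrays, and bars the group means. The naming rule required groups that do not overlap; Lcn2 goes from a mean of 3.71 to 8.66 and Rrm2 from 14.33 to 13.05, and Ddit3 is drawn for the probe set that rose by 2.79.

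Of the calls, 89 probe sets had a symbol (73 rose and 16 fell). At an unadjusted p below 0.05 there were 1517 higher and 1518 lower probe sets, 3035 in all against 1110 expected by chance. The groups did not overlap for 43.9% of probe sets, where chance gives 33.3%. The smallest called fold in this fit was 2.32. Leaving out any 1 of the 4 arrays (either vehicle array or either deltamethrin array) left 0 calls in limma, with between 1631 and 2779 probe sets at an unadjusted p below 0.05. Statistics without moderation also left 0 calls (2293 at an unadjusted p below 0.05), whereas a mean-variance trend raised the count to 806 (500 higher, 306 lower) and leaving out dim probe sets raised it to 312.

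The DNA replication and G1/S list was lower (camera adjusted p = 5.22e-14; adjusted p = 0.481 with an estimated correlation). All 30 measured genes had lower estimates, with a median log2 fold change of -0.61. Of these 0 rose, 1 fell (Rrm2) and 29 did not pass; adjusted over the list alone, 18 fell. Cdc6, which loads the replicative helicase, had an estimate of -1.60 ± 0.27 (adjusted p = 0.0865), and Uhrf1, which maintains DNA methylation at replication, one of -0.91. The mitosis and G2/M list was lower as well (camera adjusted p = 1.23e-13; adjusted p = 0.481 with an estimated correlation). All 29 measured genes had lower estimates, the median was -0.59, and 0 passed over all probe sets while 19 fell adjusted over the list alone. Mki67, the proliferation antigen Ki-67, was at -0.95 ± 0.16 (adjusted p = 0.0939) and the spindle checkpoint kinase Ttk at -0.79 ± 0.17.

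Genes of the ATF4 integrated stress response, which cells switch on when eIF2α is phosphorylated, were higher as a list (camera adjusted p = 4.72e-11; adjusted p = 0.541 with an estimated correlation). Of 28 measured genes 5 rose, 0 fell and 23 did not pass; adjusted over the list alone, 14 rose. Besides Ppp1r15a and Ddit3, the risers were the mitochondrial folate enzyme Aldh1l2 (1.79 ± 0.20), the pseudokinase Trib3 (1.40 ± 0.17) and the cystine transporter Slc7a11 (1.31 ± 0.17). Amino acid synthesis genes were spread, with Asns and Psat1 both at -0.06, Phgdh at 0.60 and Cth at 0.86. The last 2 rose adjusted over the list alone. Asns had a vehicle mean of 18.03, near the array maxima of 18.65 to 18.75, which left little room for a rise. The list's median was 0.49. The endoplasmic reticulum unfolded protein response list was not called (median -0.02, adjusted p = 0.295). It held 23 measured genes, of which 0 passed over all probe sets and 4 rose adjusted over the list alone. Those 4 were Atf6 (1.13), Ern1 (0.92), Sel1l (0.90) and Herpud1 (0.73), while the chaperone Hspa5 was at 0.20.

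The NRF2 antioxidant response list was higher (camera adjusted p = 1.98e-06; adjusted p = 0.481 with an estimated correlation). Of 24 measured genes 4 rose, 0 fell and 20 did not pass, and 6 rose adjusted over the list alone. Besides Srxn1 and Slc7a11, the risers were the haem-degrading enzyme Hmox1 (1.88 ± 0.19, adjusted p = 0.0245) and the glutathione transferase Gstm1 (1.30 ± 0.17). The median of the list was 0.19. Among members that did not pass, Nqo1 was at 0.97 and Gclm at 0.26.

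The lysosome and TFEB target list was higher (camera adjusted p = 3.01e-07; adjusted p = 0.481 with an estimated correlation). Its median was 0.43, and 0 of 25 measured genes passed over all probe sets while 10 rose adjusted over the list alone. The cysteine protease cathepsin L, Ctsl, was at 1.58 ± 0.23 (adjusted p = 0.0596) and the sialidase Neu1 at 1.15 ± 0.20. The transcription factor gene Tfe3 was at 0.90 and Tfeb at -0.31. The autophagy list was also higher (camera adjusted p = 0.000236; adjusted p = 0.481 with an estimated correlation). In it 1 of 30 genes rose, 0 fell and 29 did not pass; 6 rose adjusted over the list alone. The riser was Sqstm1, the cargo receptor p62, which rose by 2.11 ± 0.19 (adjusted p = 0.0189). Map1lc3b, the LC3B gene, was at 0.74 ± 0.20 (adjusted p = 0.203). The autophagy median was 0.18.

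The cytosolic ribosomal protein list was higher by a small amount (camera adjusted p = 2.23e-06; adjusted p = 0.647 with an estimated correlation). All 23 measured genes had higher estimates with a median of 0.31, and 0 passed either over all probe sets or adjusted over the list alone. All 23 stayed higher under quantile, cyclic loess and median scaling, but these cannot undo a shift made by the deposited normalization. Rps19 was at 0.78 ± 0.19 and Rps14 at 0.50 ± 0.17.

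The remaining called lists had mixed members. In the p53 target list 0 of 24 genes passed over all probe sets, while 6 rose and 1 fell adjusted over the list alone. The highest were Trp53inp1 (1.30 ± 0.23) and the kinase Plk3 (1.24 ± 0.20), while the p53 targets Cdkn1a and Mdm2 were at 0.24 and 0.26. The p53 list was called higher with a median of 0.18 (camera adjusted p = 0.0130; adjusted p = 0.481 with an estimated correlation). Its call was lost on ranks (adjusted p = 0.0750), without vehicle replicate 1 (adjusted p = 0.0722) and with genes of more than 1 list left out (adjusted p = 0.116). In the immediate early list 1 of 32 genes rose, the stress-inducible factor Atf3 (2.16 ± 0.17, adjusted p = 0.0134), 0 fell and 31 did not pass. Adjusted over the list alone, 4 rose (Atf3, Dusp4, Btg2 and Klf6) and 1 fell (the nuclear receptor Nr4a2, -1.03). The activity-induced genes Fos, Egr1 and Bdnf were at -0.28, -0.61 and 0.04. Of these, Fos and Bdnf were dim, with means below the median of all probe sets in both groups. The immediate early list was called higher with a median of 0.17 (camera adjusted p = 0.0232; adjusted p = 0.481 with an estimated correlation). Its call was lost without vehicle replicate 1 (adjusted p = 0.137), without deltamethrin replicate 2 (adjusted p = 0.163), without dim probe sets (adjusted p = 0.0855) and with genes of more than 1 list left out (adjusted p = 0.0517).

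**Figure D2:**
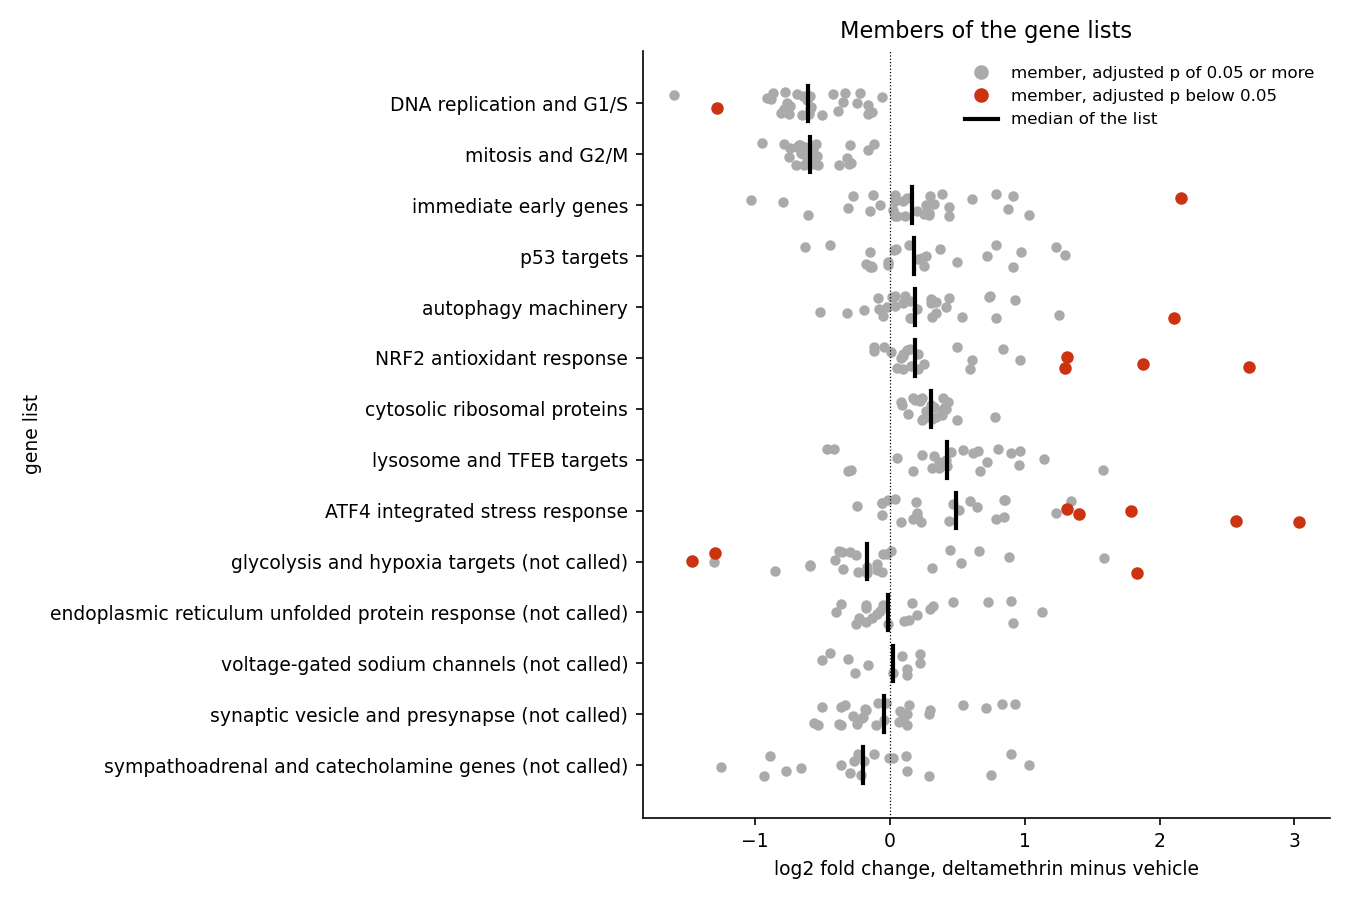
Log2 fold change of deltamethrin over vehicle (horizontal axis) of every measured member of the 9 called gene lists and of 5 that were not called (vertical axis); red points passed an adjusted p below 0.05 over all probe sets, grey points did not, and black bars are list medians. All 30 replication and all 29 mitosis genes lie left of 0 and all 23 ribosomal protein genes lie right of it, while the ATF4 list reaches 3.03 at Ppp1r15a.

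The molecular target of pyrethroids showed no called change at the transcript level. In the sodium channel list 0 of 11 measured genes passed in limma over all probe sets or adjusted over the list alone (median 0.02, mean -0.08, camera adjusted p = 0.761). The most distant from 0 were the dim beta subunit Scn4b (-0.51 ± 0.24) and the alpha subunit Scn3a (-0.44 ± 0.23). The brightest, Scn3b, was at 0.02 ± 0.18. Scn2a and Scn8a were at -0.16 and -0.26. Scn1a, Scn2b, Scn7a, Scn10a and Scn11a were also dim, with estimates from -0.31 to 0.23. The calcium channel and calcium handling list (median 0.01, adjusted p = 0.989), the potassium channel list (-0.05, adjusted p = 0.335) and the glutamate and GABA receptor list (-0.05, adjusted p = 0.761) also held 0 called genes. In these lists 11 of 27, 5 of 17 and 4 of 24 measured genes had a mean in the higher group above the median of all probe sets. Most members were thus dim, and the lack of calls does not show that these transcripts stayed level.

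Neuronal lists were not called. The sympathoadrenal and catecholamine list had a median of -0.20 (adjusted p = 0.295) and 0 of 20 genes passed over all probe sets. Adjusted over the list alone 3 rose, namely Ache (1.04), Th (0.90 ± 0.27, adjusted p = 0.242 over all probe sets) and Gch1 (0.75), and 3 fell, namely the nicotinic receptor subunits Chrna3 (-0.94) and Chrnb4 (-0.89) and the receptor tyrosine kinase Ret (-0.66). In the synaptic vesicle list (median -0.05, adjusted p = 0.956) 0 of 31 genes passed, and 2 rose adjusted over the list alone, Scg2 (0.93) and Syt4 (0.83). In the neurite and neuronal differentiation list (median -0.14, adjusted p = 0.578) 0 of 26 passed, and adjusted over the list alone Stmn4 (1.25) and Nrcam (0.74) rose and Isl1 (-1.14) fell.

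Among metabolic lists, the glycolysis and hypoxia list was not called (median -0.17, adjusted p = 0.295), although 1 of 28 genes rose, Ndrg1 (1.83 ± 0.20), and 2 fell, Pdk1 and Ankrd37. Adjusted over the list alone 4 rose and 4 fell. In the fatty acid oxidation and PPAR target list (median -0.02, mean 0.24, adjusted p = 0.295) 1 of 14 rose, the lipid droplet protein gene Plin2 (2.17 ± 0.22, adjusted p = 0.0261), and 2 rose adjusted over the list alone. Fatty acid synthesis (median -0.20, adjusted p = 0.101), cholesterol synthesis (-0.13, adjusted p = 0.295) and oxidative phosphorylation (0.02, adjusted p = 0.645) held 0 called genes. The fatty acid synthesis list was called lower without vehicle replicate 1 (adjusted p = 0.0158), and 2 of its genes fell with a mean-variance trend. Bnip3 was the single call among 19 genes of mitophagy and mitochondrial dynamics (median -0.05, adjusted p = 0.761). Mitochondrial biogenesis and chaperones (median 0.12, adjusted p = 0.130) held 0 called genes, with the mitochondrial protease gene Lonp1 at 1.84 ± 0.28 (adjusted p = 0.0728). Of that list, 1 gene rose adjusted over the list alone.

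The xenobiotic metabolism list was not called (median 0.04, adjusted p = 0.591) and held 0 called genes. Only 5 of its 21 measured genes had a mean in the higher group above the median of all probe sets. The dioxin-inducible genes Cyp1a1 and Cyp1b1 were dim in both groups, with estimates of -0.09 ± 0.17 and 0.26 ± 0.29. The heat shock (median 0.11, adjusted p = 0.569), metallothionein (0.00, adjusted p = 0.487), proteasome (0.03, adjusted p = 0.726) and glutathione and thioredoxin (-0.04, adjusted p = 0.956) lists held 0 called genes. So did apoptosis regulators (0.04, adjusted p = 0.419) and the interferon response (0.05, adjusted p = 0.291). In the NF-kB list (median 0.10, adjusted p = 0.154) Tnfaip2 was the single call among 27 genes, and the list was called higher without deltamethrin replicate 1 (adjusted p = 0.0117). Markers of other cell types held 0 called genes and were not called as lists. Their medians were -0.17 for astrocytes (adjusted p = 0.406), 0.03 for oligodendrocytes and Schwann cells (0.650), 0.04 for microglia and macrophages (0.761), and -0.12 for fibroblasts (0.726).

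Over the 36 lists, camera with the preset correlation called 9, of which 7 were higher and 2 lower. With an estimated correlation 0 were called, and fry, which tests whether the genes of a list move one way on balance, called 0 after adjustment. Member counts over all probe sets depended on the variance model. With a mean-variance trend, 14 genes of the replication list and 16 of the mitosis list fell, and 14 of the ATF4 list, 9 of the lysosome list, 6 of the autophagy list, 5 of the NRF2 list and 2 of the ribosomal protein list rose. With it, 5 rose and 1 fell in the p53 list, 3 rose and 1 fell in the immediate early list, 4 rose and 4 fell in the glycolysis and hypoxia list, and 4 rose in the unfolded protein response list. Among neuronal lists with that trend, 4 rose and 2 fell in the synaptic vesicle list, 3 rose and 2 fell in the neurite list, and 1 rose and 2 fell in the sympathoadrenal list, while the sodium channel list still held 0 calls.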

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

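The count of 96 changed probe sets (79 higher, 17 lower) depended on the variance model and the threshold. Leaving out 1 array, with the lone array of a group assumed to vary like the other group, gave 0 changed, 0 higher and 0 lower each time. The unadjusted counts were 1631 without vehicle replicate 1, 2027 without vehicle replicate 2, 2277 without deltamethrin replicate 1 and 2779 without deltamethrin replicate 2. In a simulation with 1 vehicle array left out, 0% of 4-fold changes were recovered, so these fits say little about stability. All 96 calls kept their direction in each of them. They were picked on these same arrays, so this was close to fixed in advance and is no sign of stability. With the replicate number as a block in limma, 0 probe sets were called (0 higher, 0 lower) against 3221 at an unadjusted p below 0.05, although the block recovered 91% of simulated 4-fold changes; the cause was not tested. The deviations of replicate 1 correlated at 0.127 across all probe sets and 0.246 across those above the median level. With only 2 numbers per group and no shared day or culture in the labels, the numbers were not taken to pair the arrays. No moderation gave 0 (0 higher, 0 lower), with 2293 unadjusted. A mean-variance trend gave 806 (500 higher, 306 lower, 62% higher against 82.3%) and included all 96. Leaving out dim probe sets, which tests fewer of them, gave 312 (239 and 73). An unadjusted p below 0.05 with a 2-fold minimum gave 320 (243 and 77), an adjusted p below 0.01 gave 5 (5 and 0), and a test against a 1.2-fold change gave 39 (38 and 1). The cause of the differences between variance models was not tested. Quantile normalization, cyclic loess, centring, robust moderation, array weights, a 2-fold minimum and 1 probe set per gene stayed within 1.5 times the count.

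The count of 9 called lists was 0 with an estimated correlation and 0 with fry; the other alternatives gave 7 to 10. The 9 lists kept their direction without each array and under each scaling. They were called on these same arrays, and the scalings hardly moved the median fold change of all probe sets. The kept directions were thus close to fixed in advance and are no sign of stability. The block ended no call of a list. Calls of the p53 and immediate early lists were lost under some alternatives, as given with those lists; the other 7 kept theirs except with an estimated correlation and fry. Fatty acid synthesis and NF-kB gained a call when 1 array was left out. Without detection calls, the depth of dim probe sets over background stays unknown.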

Other observations

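The tests of dilution, of dim probe sets and of the ATF4 list against the unfolded protein response list, along with the second lists, were chosen after the results they bear on were seen, and so were the genes named next.

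Several called genes lay outside the fixed lists. Renbp, which interconverts N-acetylglucosamine and N-acetylmannosamine, rose by 2.19 on the log2 scale. Gnpda1, which turns glucosamine 6-phosphate back into fructose 6-phosphate, rose by 1.91, Gnpnat1 of UDP-N-acetylglucosamine synthesis by 1.44, and the related Uap1l1 by 2.07. The sterol carrier gene Stard5 rose by 2.65, the acyl-CoA thioesterase Acot2 by 1.97, the phospholipid transfer protein Pltp by 1.70 and the cholesteryl ester hydrolase Nceh1 by 1.35. The fixed lists of fatty acid and cholesterol metabolism were not called with all 4 arrays; fatty acid synthesis was called lower without vehicle replicate 1 (adjusted p = 0.0158). Flcn, the folliculin gene, rose by 1.99 and Lgals8, whose product galectin-8 binds damaged vesicles, by 1.76. Among the falls were Lgr5 (-1.27), a receptor for R-spondins, the neurturin receptor gene Gfra2 (-1.29) and the PCNA-associated factor Pclaf (-1.22).

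The 59 measured replication and mitosis genes all had lower estimates, with a joint median of -0.60. Random lists matched on brightness had medians whose lowest 2.5% began at -0.115, and 0 of 10000 reached the observed median, which argues against a normalization trend with brightness. RNA of other cells would dilute the line's own transcripts alike. The 33 bright neuronal and presynaptic genes had a median of -0.11, with a 95% bootstrap interval whose lower end was -0.27, which argues against dilution as the whole account. A lower share of dividing cells may account for the shift, and a difference in cell density or batch between the groups stays open and untested.

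Calls were mostly higher (82.3%), although unadjusted p-values below 0.05 were evenly split. Among probe sets with a vehicle mean above 10, 24 of 32 calls were higher, or 75% (exact binomial 95% interval 56.6% to 88.5%). The floor of dim probe sets thus does not account for all of the excess, although the interval treats probe sets as independent. The share was at least 82.5% after cyclic loess and after median centring. These moved the median fold change of all probe sets by at most 0.02 on the log2 scale and cannot undo a shift made by the deposited normalization, so an effect of array centring stays open. With a mean-variance trend it was 62%, so part of its size depends on the variance model.

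Bnip3, Pdk1 and Ankrd37 fell and Adm was at -1.30, all of them known targets of hypoxia-inducible factor. A lower activity of that factor may underlie these values. A second list of 32 targets, none in the fixed lists, had 22 lower estimates, a median of -0.19 and a camera p of 0.0448, and 0 members passed alone. The p was 0.149 with an estimated correlation and 0.0597 after adjustment over the 4 second-list tests, and Ndrg1, another target, rose, so the evidence is weak.

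The lysosome list's shift may extend to lysosomal genes at large. A second list of 43 such genes had 33 higher estimates, a median of 0.39 and a camera p of 6.42e-09 (0.161 with an estimated correlation), although 0 members passed alone. The highest were the chloride transporter Clcn7 (1.13), the TFEB regulator Fnip1 (1.13) and Cd63 (1.09).

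Whether amino sugar metabolism rose broadly stays open. A list of 18 such genes, written after 4 of them were seen to rise, was higher (median 0.25, camera p of 0.000225, and 0.187 with an estimated correlation). Its 14 members that were not called had a median of 0.16 and a camera p of 0.257, but a list without its called genes excludes nothing. The synthesis enzymes Gfpt1 and Uap1 were at 0.13 and -0.24. Set against each other, the ATF4 list (28 genes, median 0.49) and the unfolded protein response list (23 genes, median -0.02) differed by a camera p of 0.00348 with the preset correlation and 0.268 with an estimated one, so whether they differ stays open.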
